A study of Mus musculus with 6 samples.

How the data were processed

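RNA from mouse pro-B cells, an early stage of B-cell development in the bone marrow, was sequenced in 6 libraries. The labels put 3 libraries in a control group and 3 in a Mef2c/d knockout group, and both groups carried the Mb1Cre recombinase, which is active in the B lineage. Per the labels' protocols, the cells were sorted as lineage-negative, CD19-positive, CD43-high and B220-low, poly(A) RNA was selected, and libraries were made with 1 of 2 kits and sequenced on an Illumina HiSeq instrument. The kit used for each library is not given in the sources used here. The labels number the replicates of each group from 1 to 3 and do not say that they came from separate animals, so p-values measure the spread between these libraries, which may be technical in part.

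The deposited table has 38918 rows, each a gene with its mm10 region, and 127 columns. Per the file headers, the authors deposited for each library the counts of total exon reads, unique exon reads, total gene reads and exon-exon (junction) reads, without normalization. The CASAVA version 1.8.2 and mm10 names come from the submitters' processing notes. The aligner, the counting tool, the gene annotation and the strand setting are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart. Total exon reads include reads that fit several positions, and genes for which under 65% of exon reads were unique are named as such beside their values. The authors' RPKM columns and their columns of group comparisons were not used.

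Total exon reads were tested as deposited. Of 38717 gene symbols, 201 further rows repeated a symbol, and the row with the highest mean was kept. Genes were filtered with the default settings of filterByExpr (minimum count 10, minimum total count 15), which left 13843 genes, and libraries were scaled with TMM factors. The groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes, and an adjusted p under 0.05 was called. Fold changes are log2 values of the libraries labelled knockout against the control libraries. Expression is given in CPM, counts scaled to a common library size of 1e6, from TMM-scaled exon reads, as mean ± SD over the 3 libraries of a group. The rank test of 3 libraries against 3 cannot give an exact p below 0.1, so calls rest on the model's spread shared across genes.

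The 26 gene lists, the rule for named genes and the alternative settings were set before the data were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and the rotation test fry were alternatives. Named genes were Mef2a, Mef2b, Mef2c, Mef2d and Klf2, the 12 largest rises and the 12 largest falls, and up to 4 called members of each list with the smallest p (2 where none was called). The largest rises and falls had to be called, with groups that did not overlap and a mean of at least 5 CPM in the higher group, and segments of immunoglobulin and T-cell receptor genes and Gm and Rik models were left out. A few list members outside this rule are named in the text and were chosen after their values were seen. They are Cd19, Cd79a, Vpreb1, Igll1, Dusp1, Fos, Junb, Jund, Nr4a2, Kit, Cd5, Rorc, Cd2, Ltb, Hspa1a, Pax5, Blk, Ccnd2, Cish, Cd3d, Cd3e, Cd3g, Cd34, Meis1, Mpo, Xist, Jun, Egr1, Ier2, Atf3, Trbc2, Hlf, Gata2, Hoxa9, Mecom, Mpl, Rag1, Rag2, Lars2, Gm26924, Ighm, Igkc and the muscle and family members in the closing section.

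Replicates were compared before they were averaged. Controls 2 and 3 differed by 2.19 times the sampling noise (chi-square 27919.9 on 12727 degrees of freedom), and the other pairs within a group differed by 66.0 to 204 times. That ratio does not show whether they are separate samples or 1 sample prepared more than once, and n counts libraries throughout. Both were kept, and a fit with their counts summed into 1 sample was added after the data were seen. Replicates 1 of both groups stood apart from replicates 2 and 3 in depth and in the share of junction reads. The replicate numbers were checked for pairing through the correlation of deviations from the group means across genes. Same-numbered libraries correlated at 0.605, 0.352 and 0.272, all over the 0.1 set beforehand, so the numbers were taken to pair the libraries. Control 2 with knockout 3 (0.274) and control 3 with knockout 2 (0.353) correlated as well, so the pairing shown is that of replicate 1 against the others. The fit on group alone stayed the main one, because it was set before the data were examined and no label states a pairing. Values with the replicate block are given where they change the call of a list or of a gene named here, or move a count by over 1.5 times. The block keeps controls 2 and 3 as separate libraries, so its calls may lean on their small spread.

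The fit was tested on simulated counts for 13679 genes with 200 changed genes, 3 libraries against 3. It recovered 10.4% of genes changed 1.5-fold, 71.6% of genes changed 2-fold and 97.0% of genes changed 4-fold, and 4.80% of its 125 calls were false. With no change simulated it made 0 calls. The simulated libraries were independent, without near-identical controls or a shift shared by replicates 1. With only 200 genes changed, an adjusted p under 0.05 also required a smaller p than in the real fit, where 3505 genes were called. These rates may therefore not hold for the real libraries. Alternatives covered RLE, upper quartile and no scaling factors, DESeq2 1.42.0, limma-voom, filters, thresholds, each library and each replicate number left out, and repeated symbols kept apart or summed. They also covered the removal of immunoglobulin segments, Y-linked genes and Xist. The fits on unique exon reads and with a term for replicate 1 against the others, and the list tests without a replicate number in both groups, were added after the data were seen.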

Results

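The table held exon reads of sorted mouse pro-B cells from 3 control libraries and 3 libraries labelled Mef2c/d knockout. Mef2c and Mef2d are transcription factors of the myocyte enhancer factor 2 family, and Klf2 is a zinc-finger transcription factor of lymphocytes. The labels name a search for targets of Mef2c and Mef2d in B-cell progenitors, and the design text names genes regulated by Klf2. The control libraries held 74634675, 33756736 and 28837160 exon reads, and the libraries labelled knockout held 65645062, 43689565 and 40892267. Junction reads made up 38.6% and 37.4% of exon reads in replicates 1 and between 19.7% and 20.1% in the other 4 libraries. Transcripts of the B lineage were abundant in both groups, with Cd19 at 862 ± 39.5 CPM in controls and 1202 ± 34.6 CPM in libraries labelled knockout (n = 3 libraries each, as for all values below).

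**Figure D1:**
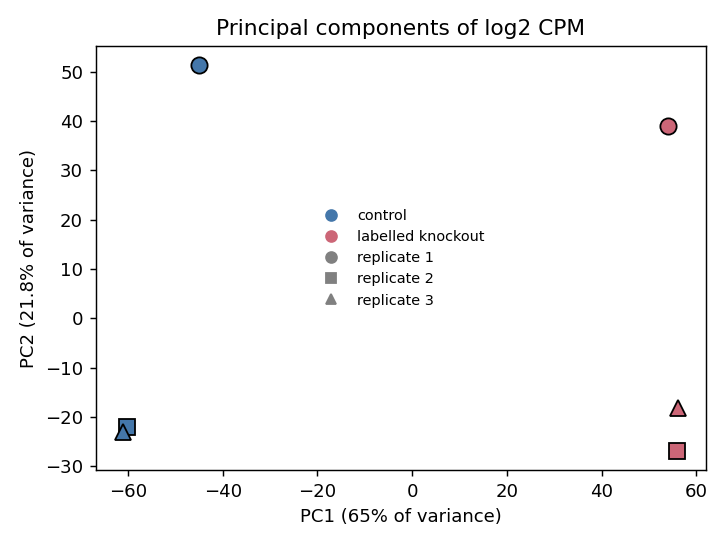
Principal components of log2 CPM over 13843 genes, with 1 point per library, color for group and marker shape for replicate number. PC1 (65% of variance) separates the groups, and PC2 (21.8%) separates replicates 1 from replicates 2 and 3, with controls 2 and 3 almost on the same point.

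The targeted genes were examined first, because they bear on the labels. Exon reads of Mef2c (chromosome 13, 83504034 to 83667079, mm10) were not lower in the libraries labelled knockout. They measured 184.5, 141.5 and 134.6 CPM in controls and 242.2, 226.3 and 193.3 CPM in libraries labelled knockout (log2 fold change 0.52, SE 0.15, adjusted p = 0.0470). That call was lost when control 2 (adjusted p = 0.163), control 3 (0.161), knockout 1 (0.0776), knockout 2 (0.0999), replicate 2 of both groups (0.301) or replicate 3 of both groups (0.173) was left out. It was also lost when controls 2 and 3 were summed (adjusted p = 0.161). Mef2d (chromosome 3, 88142372 to 88172086) stood at 756 ± 73.7 CPM in controls and 695 ± 65.3 CPM in libraries labelled knockout (log2 fold change −0.12, SE 0.12, adjusted p = 0.519), and it was lower in each of the 3 same-numbered pairs. Mef2a, a family member that was not targeted, rose from 86.99 ± 12.04 to 121 ± 7.53 CPM (log2 fold change 0.47, SE 0.12, adjusted p = 0.0300), a call that was lost with controls 2 and 3 summed (adjusted p = 0.123) and with control 2, control 3, knockout 3, replicate 2 or replicate 3 left out (adjusted p from 0.0547 to 0.223). Mef2b had 0 exon reads in every library, so it was not detectable at this depth. Of the 3 family members tested, 2 were called higher and 0 lower. The counts cover all annotated exons of each gene, and the labels do not give the deleted part, so these values do not check the labels. The libraries are therefore called labelled knockout, or knockout 1 to 3 for the single libraries by their label, and each direction below rests on those labels.

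**Figure D2:**
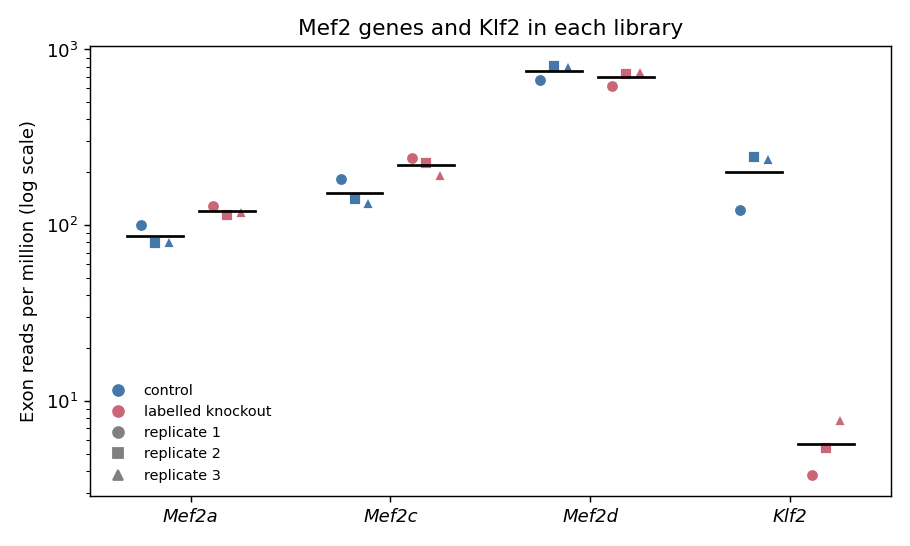
Expression in CPM (log scale) of Mef2a, Mef2c, Mef2d and Klf2 in each library, with color for group, marker shape for replicate number and a black bar at the group mean. Klf2 lies at 122 to 244 CPM in controls and 3.79 to 7.82 CPM in libraries labelled knockout, while Mef2c and Mef2d show no such drop.

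Klf2 (chromosome 8, 72319033 to 72321656) was 35.6-fold lower in the libraries labelled knockout. It fell from 201 ± 68.2 CPM to 5.69 ± 2.03 CPM (log2 fold change −5.15, SE 0.40, adjusted p = 0.000289), and all 3 libraries of that group lay below all 3 controls. Over the whole transcriptome 3505 of 13843 genes were called, 2021 higher and 1484 lower in libraries labelled knockout. Of these, 1804 changed by at least 1 on the log2 scale, with 1168 higher and 636 lower. The groups did not overlap for 44.4% of tested genes, against 10% by chance for 6 independent libraries. Near-identical controls 2 and 3 would raise that chance level. The count depended on the libraries included. It was 2048 (1252 higher, 796 lower) with the counts of the near-identical controls 2 and 3 summed, 1978 without control 2 and 2010 without control 3. It was 2503 without knockout 2 and 2268 without knockout 3, and knockout 3 had the highest share of reads outside exons. It was 6389 without replicate 1 in both groups, 849 without replicate 2 and 793 without replicate 3. In the last 2 of these fits, every gene named by the fixed rule with a log2 change under 1 in size lost its call, as did Kdr, P4ha1 and Aldoc in both, Shank2 without replicate 2 and E2f1, Gadd45b and Il2rg without replicate 3. With the replicate block, which takes up the difference of replicates 1 from the others, 6283 genes were called (3089 higher, 3194 lower), and they included 3502 of the 3505. The counts of 6283 and 6389 keep controls 2 and 3 as separate libraries, so their added calls may lean on the small spread between those controls.

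The largest rises were in genes nearly silent in controls. C4bp, a complement-binding protein, had 4 reads summed over the 3 controls and 3006 in the libraries labelled knockout (19.3 ± 3.27 CPM, log2 fold change 9.28, SE 0.53, adjusted p = 0.000118). Ly6a, which encodes the stem-cell and lymphocyte surface antigen Sca-1, rose from 3.71 ± 0.969 to 264 ± 44.7 CPM, a 70.6-fold increase (log2 fold change 6.14, SE 0.26, adjusted p = 4.82e-05). The inhibitory receptor gene Ctla4 rose from 0.143 to 11.03 CPM (log2 fold change 6.36, SE 0.41) and the growth factor gene Pgf from 0.535 to 37.2 CPM (6.06, SE 0.26). The glutamate receptor gene Grm6 rose by 6.35, Ttc18 by 6.09, the cadherin gene Cdh17 by 5.90 and the laminin gene Lama4 by 5.53 on the log2 scale. Clic6 rose by 5.83 (SE 0.95) with wide scatter, 20.4 ± 21.1 CPM in libraries labelled knockout. Prss23 (5.46), Serpina3g (5.28) and Gimap7 (5.27) completed the 12, but only 46.2%, 17.2% and 63.7% of their exon reads were unique, so reads of related genes cannot be excluded. All 12 had adjusted p values of 0.00514 or less.

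The largest falls were of the same order. Col5a3, a collagen gene, fell from 97.1 ± 45.6 to 0.191 ± 0.130 CPM (log2 fold change −9.05, SE 0.64, adjusted p = 0.000220). Fosb, a subunit of the AP-1 transcription factor, fell from 113 ± 106 to 0.448 ± 0.129 CPM (log2 fold change −8.01, SE 0.86, adjusted p = 0.000993), with 235 CPM in control 1 and 51.8 and 51.7 CPM in controls 2 and 3. Polm, which encodes the end-joining DNA polymerase mu, fell from 202 ± 58.3 to 4.73 ± 0.818 CPM (log2 fold change −5.41, SE 0.29, adjusted p = 9.79e-05). The orphan receptor gene Gpr12 had a log2 fold change of −8.07, the scaffold gene Shank2 −7.23, the insulin receptor substrate gene Irs1 −7.13 and the kinase gene Plk2 −5.73. Rbm24 (−6.90) and Srpk3 (−6.44), an RNA-binding protein and a kinase known from muscle, fell with Lrrc10b (−5.90) and the cytokine gene Il33 (−5.68). Adam19, a membrane metalloprotease gene, fell from 267 ± 78.5 to 4.69 ± 2.94 CPM (−5.83), with 46.4% of its reads unique. Several of these falls and rises depend on few reads in the lower group, with 7 (Shank2), 12 (Gpr12) and 17 (Irs1) summed over the libraries labelled knockout and 15 (Ttc18), 17 (Ctla4) and 19 (Grm6) over the controls, so the size of their fold changes is uncertain. The Shank2 call was lost without replicate 2 in both groups (log2 fold change −6.71, adjusted p = 0.0514).

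**Figure D3:**
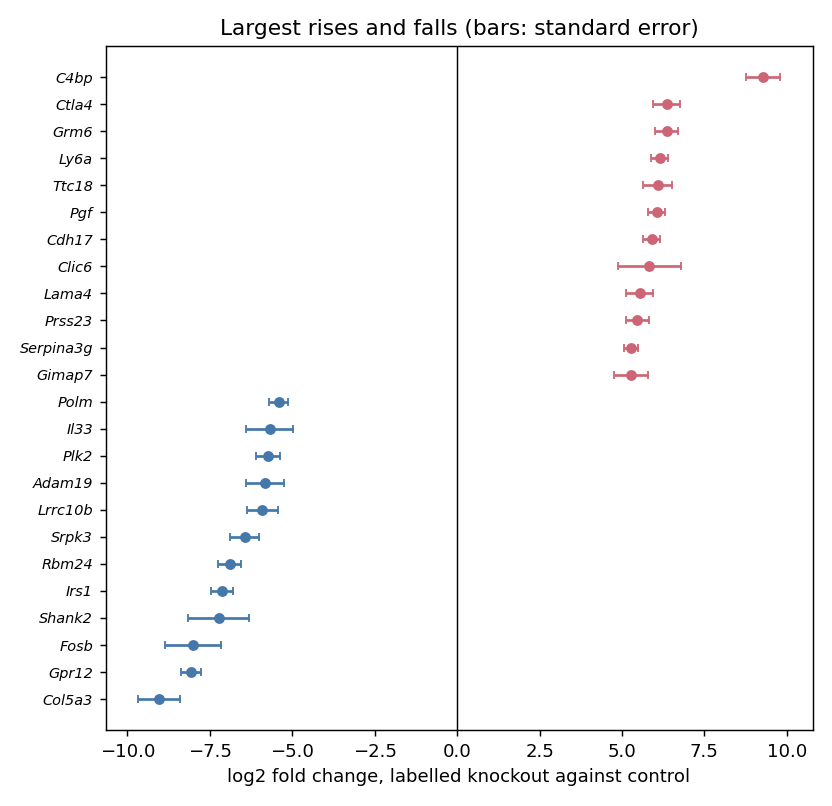
Log2 fold changes of the 12 largest rises and 12 largest falls, labelled knockout against control, with bars for the standard error. Rises run from 5.27 (Gimap7) to 9.28 (C4bp), and falls from −5.41 (Polm) to −9.05 (Col5a3).

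For the fixed gene lists, each count below gives members called over all genes tested. Where the count adjusted over the list alone differs it follows, and otherwise both were equal. Of 25 lists tested with camera, 7 were called, 3 higher and 4 lower, and 0 were called with an estimated correlation (smallest adjusted p = 0.435). With fry, which asks whether members move 1 way on balance without comparing them with other genes, 14 were called. The estimate exceeded the preset 0.01 in all 7 called lists, from 0.0267 (multipotent and lymphoid progenitors) to 0.647 (homologous recombination and replication repair). A high estimate is not the only source of larger p values with that setting. In the apoptosis list the estimate was −0.0243, below the preset, and the unadjusted camera p still rose from 0.018 to 0.0621. The camera calls therefore depend on how the test was set and are weaker evidence than the calls of single genes. Mixed splits of the same 6 libraries gave up to 10 called lists, but they keep part of the group difference and cannot grade these calls.

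Immediate early genes, transcription factors and regulators that cells induce within minutes of a stimulus, were lower as a group. Of 25 members tested, 11 fell and 0 rose (12 lower when adjusted over the list alone), with a median log2 fold change of −1.27 (camera adjusted p = 9.66e-05; adjusted p = 0.660 with an estimated correlation). Fos fell by 5.41 (SE 0.78), Klf4 by 3.94 (SE 0.18), Jund by 2.49, Nr4a2 by 2.54, Dusp1 by 1.78 and Junb by 1.72 on the log2 scale, the largest adjusted p of these 6 being 0.0374 (Dusp1). The Jund and Dusp1 calls were lost with controls 2 and 3 summed (adjusted p = 0.0675 and 0.0551). Zfp36 (−1.62) and Dusp5 (−1.05) also fell. Control 1 stood apart within its group, with Fos at 358 CPM against 97.8 and 92.7 CPM, and Egr1 at 140 CPM against 12.7 and 11.7 CPM. Egr1 stood at 18.3, 16.3 and 14.4 CPM in libraries labelled knockout and was not called (log2 fold change −1.76, SE 0.94, adjusted p = 0.226). Among 16 genes of stress and RNA quality, 1 rose and 4 fell (5 when adjusted over the list alone, 8 with the replicate block; camera adjusted p = 0.133). The heat shock genes Hspa1a (−4.13, SE 1.04) and Hspa1b (−2.83, SE 0.32) were among the falls, with 19.8% and 31.5% of their reads unique, together with Gadd45b (−2.71) and Neat1 (−0.70; adjusted p = 0.0579 with controls 2 and 3 summed).

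Genes of the cell cycle and of DNA replication were lower by small amounts. In the S phase list 14 of 24 members fell and 0 rose (16 lower and 1 higher when adjusted over the list alone), with a median log2 fold change of −0.42 (camera adjusted p = 1.62e-05; adjusted p = 0.589 with an estimated correlation). E2f1, a regulator of the G1 to S transition, fell by 1.07 (SE 0.11, adjusted p = 0.000850), and Rrm2, Cdc6 and Mcm2 fell by 0.66, 0.63 and 0.55. In the G2 and M phase list 9 of 24 fell and 0 rose (10 lower when adjusted over the list alone; median −0.52; camera adjusted p = 1.62e-05; adjusted p = 0.435 with an estimated correlation). The mitotic genes Aurka, Birc5, Ccnb2 and Bub1b fell by 0.52, 0.53, 0.60 and 0.51. Homologous recombination and replication repair had 8 lower of 20 and 0 higher (10 lower when adjusted over the list alone; median −0.50; camera adjusted p = 0.000166; adjusted p = 0.660 with an estimated correlation), among them Bard1 (−0.64), Rad51 (−0.57), Rad54l (−0.71) and Rpa2 (−0.45). Blocking on the replicate raised the lower members to 21, 24 and 16 in these 3 lists, with 1 member of the S phase list higher, and summing controls 2 and 3 reduced them to 8, 2 and 6, with Aurka, Birc5 and Ccnb2 among the calls lost.

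Lists of early progenitor and T-lineage genes were higher. Of 18 members of the multipotent and lymphoid progenitor list, 10 rose and 2 fell (12 and 2 when adjusted over the list alone; median 0.70; camera adjusted p = 0.00364; adjusted p = 0.435 with an estimated correlation). The cytokine receptor gene Flt3 rose from 8.03 ± 1.92 to 96.8 ± 18.1 CPM (log2 fold change 3.58, SE 0.22, adjusted p = 0.000155), Cd27 rose by 3.78 (48.9% of reads unique) and Kit by 1.69. Gfi1b, known from erythroid cells and platelets, fell by 2.72. Cd34 stood at 1.67 ± 1.43 and 0.591 ± 0.484 CPM (55.5% of reads unique) and was not called, though it was lower with the replicate block (adjusted p = 0.0299). In the list of T, natural killer and innate lymphoid cells 10 of 25 rose and 0 fell (11 higher when adjusted over the list alone; median 1.11; camera adjusted p = 9.66e-05; adjusted p = 0.435 with an estimated correlation). The signalling adaptor Lat rose from 16.6 ± 3.56 to 279 ± 59.2 CPM (log2 fold change 4.07, SE 0.23, adjusted p = 0.000118). Cd5 rose by 3.08, Rorc by 4.22 from 0.0344 to 0.821 CPM, the kinases Lck and Zap70 by 1.87 and 1.40, and Cd247 by 1.55 (34.8% of reads unique). The T-cell receptor component genes Cd3d, Cd3e and Cd3g stayed at means of 0.574 CPM or less and were not called. Of 15 dendritic cell genes 2 rose and 0 fell, Flt3 and Ly6d (2.02), with a median of −0.23 against an upward camera statistic (adjusted p = 0.834), and 3 fell with the replicate block.

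Lists of myeloid, erythroid, stromal and plasma cells, types other than the sorted pro-B cells, were not called by camera. None of the 31 myeloid genes was called with edgeR, nor over the list alone, and 1 fell with the replicate block (median 0.21, with camera pointing down, adjusted p = 0.938). The list was called higher without knockout 2 (adjusted p = 0.000685) and without replicate 2 in both groups (0.00148). Chi3l3 (log2 fold change 1.06, SE 0.60) and Fcgr4 (0.95, SE 0.56) had the smallest p of that list and were not called, but both were called without knockout 2 (adjusted p = 0.0220 and 0.0398). Mpo, a granule enzyme gene, measured 69.3 ± 39.9 and 50.5 ± 21.8 CPM and was the member lower with the block (adjusted p = 0.0159). Among 18 erythroid and megakaryocyte genes the carbonic anhydrase gene Car2 rose (1.88) and the transferrin receptor gene Tfrc fell (−0.63), and 2 fell with the replicate block (camera adjusted p = 0.904). Of 11 stromal and endothelial genes, Kdr fell from 2.202 to 0.290 CPM (−2.85; adjusted p = 0.114 without replicate 2 and 0.0915 without replicate 3 in both groups) and 0 rose, and 2 fell with the replicate block (camera adjusted p = 0.834). Of 10 plasma cell genes 4 rose and 3 fell (4 lower when adjusted over the list alone; camera adjusted p = 0.842). Mzb1 rose by 1.57, while Sdc1, which encodes CD138, and Igj had log2 fold changes of −3.26 and −2.70. The 5 sex-linked genes were not called (camera adjusted p = 0.904) and varied within groups. Ddx3y, a Y-linked gene, stood at 0.0545, 28.7 and 29.9 CPM in controls and 23.4, 6.61 and 0 CPM in libraries labelled knockout. Eif2s3y had means of 26.5 ± 22.9 and 9.99 ± 11.3 CPM, and Xist, with 3.81% of its reads unique, was between 1075 and 3696 CPM in every library. The Y-linked levels argue against 1 cell sample behind all 3 controls, and against 1 behind the 3 libraries labelled knockout. Controls 2 and 3 matched (Eif2s3y at 38.6 and 40.8 CPM), so for them the question stays open.

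Genes of B-cell identity and signalling moved in both directions. In the pre-B cell receptor list 11 of 26 rose and 5 fell (camera adjusted p = 0.606; 7 higher and 4 lower with controls 2 and 3 summed). The surrogate light chain genes Igll1 (1.56) and Vpreb1 (1.58) and the adaptor gene Bank1 (3.33, SE 0.21) rose, as did Cd79a (0.97). The kinase gene Syk fell from 1550 ± 226 to 450 ± 21.4 CPM (log2 fold change −1.79, SE 0.14, adjusted p = 0.000280). Cd72 (−1.98), Cd22 (−2.71), both inhibitory receptors, and the kinase gene Blk (−1.37) also fell. Among 30 B-lineage transcription factors 4 rose and 9 fell (camera adjusted p = 0.176; 2 higher and 6 lower with controls 2 and 3 summed). Bach2 fell from 1027 ± 189 to 107 ± 13.0 CPM (log2 fold change −3.27, SE 0.18, adjusted p = 0.000118), with 76.9% of reads unique. Irf4 fell by 1.96, Ikzf1, which encodes Ikaros, by 1.38 and Pax5 by 0.85, while Bcl11a rose by 1.81 with 30.5% of its reads unique. Of 24 genes of later B-cell stages 8 rose and 3 fell (9 and 4 when adjusted over the list alone; camera adjusted p = 0.176, 0.0442 with the replicate block and 0.786 with an estimated correlation). Cd86, a costimulatory ligand, rose from 0.921 to 27.6 CPM (4.90, SE 0.17), the chemokine receptor gene Cxcr5 rose by 3.78, Ltb by 3.51 and Ms4a1, which encodes CD20, by 1.68 (43.2% of reads unique). Fcrla (−2.24) and Cd2 (−4.45) fell.

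In the list of V(D)J recombination and end joining 4 of 23 rose and 2 fell, and 8 rose and 7 fell with the replicate block (camera adjusted p = 0.904). The recombinase genes Rag1 (log2 fold change 1.72, SE 0.75) and Rag2 (1.02, SE 0.46) were not called (adjusted p = 0.145 and 0.153). Both were called higher with the replicate block (adjusted p = 0.000817 and 0.000526). Dntt, which encodes terminal deoxynucleotidyl transferase, rose from 471 ± 97.6 to 1277 ± 108 CPM (log2 fold change 1.44, SE 0.17, adjusted p = 0.00134). Polm, described above, and Hmgb2 (−0.83, 56.5% of reads unique) fell, and Xrcc6 rose by 0.67 (53.8% of reads unique). Among the 9 genes of Klf2 and its trafficking targets 3 rose and 1, Klf2 itself, fell (camera adjusted p = 0.391). Sell, which encodes the homing receptor L-selectin, rose from 126 ± 5.13 to 494 ± 55.4 CPM (log2 fold change 1.97, SE 0.11, adjusted p = 0.000125). Klf3 rose by 1.15 and the chemokine receptor gene Cxcr3 by 3.03 from 0.474 CPM. Of 11 Mef2 partners and class IIa deacetylases 1 rose and 2 fell (camera adjusted p = 0.586). The falls were the deacetylase genes Hdac9 (−2.94, SE 0.39) and Hdac5, from 502 ± 149 to 97.5 ± 17.8 CPM (−2.36, SE 0.26), and the rise was the corepressor gene Ncor2 (0.85).

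The interferon response list had 9 of 26 members higher and 0 lower (9 and 1 when adjusted over the list alone), with a median of 0.44 (camera adjusted p = 0.000563; adjusted p = 0.660 with an estimated correlation). The list was not called without replicate 1 in both groups (adjusted p = 0.0550). The guanylate-binding protein gene Gbp2 rose from 15.4 ± 1.10 to 196 ± 13.9 CPM (log2 fold change 3.67, SE 0.11, adjusted p = 2.13e-05), Gbp3 rose by 2.27, Ifi44 by 1.86 and the transcription factor gene Stat1 by 1.28. Of 23 adhesion and chemokine receptor genes 11 rose and 5 fell (camera adjusted p = 0.0530). That list lay near the threshold and was called with controls 2 and 3 summed (adjusted p = 0.0484), on unique reads (0.0264), with fry (0.000924), without knockout 2 (0.0403) and without replicate 2 in both groups (0.0499). Camera did not call it with the replicate block (adjusted p = 0.0632) or with an estimated correlation (0.435). The sphingosine phosphate receptor gene S1pr3 rose from 1.14 to 28.3 CPM (4.63, SE 0.14) and Bst1 by 1.85, while the focal adhesion kinase relative Ptk2b fell by 1.81. In the list of IL-7 receptor signalling and survival, the cytokine pathway that pro-B cells depend on, 6 of 17 rose and 2 fell (camera adjusted p = 0.391). Ccnd2 (1.45), Cish (1.91, 34.0% of reads unique), Bcl2 (0.99) and Jak3 (0.95) rose and Mycn fell by 1.88. Il2rg rose by 1.57, but 9.41% of its reads were unique and the call was lost on unique reads (adjusted p = 0.0985) and without replicate 3 in both groups (0.0894).

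Of 19 apoptosis regulators 5 rose and 1 fell (camera adjusted p = 0.0530, and 0.0405 with the replicate block, where 8 rose; 3 higher and 0 lower with controls 2 and 3 summed, where camera gave 0.0484). With an estimated correlation camera gave an adjusted p of 0.435. The death receptor gene Fas rose by 1.90 and Casp8 by 0.41, and Casp9 fell by 0.56, the last 2 not called with controls 2 and 3 summed (adjusted p = 0.0789 and 0.0511). Among 18 p53 target genes 4 rose and 5 fell (2 and 2 with controls 2 and 3 summed), with a median of 0.15 and a mean of −0.13 (camera pointing down, adjusted p = 0.987). Plk2 fell as given above, Aen fell by 0.50 and Sesn1 rose by 0.65. In the glycolysis and hypoxia list 3 of 24 rose and 2 fell, 5 rose and 6 fell with the replicate block, and 2 rose and 1 fell with controls 2 and 3 summed (camera adjusted p = 0.951). The pyruvate dehydrogenase kinase gene Pdk1 rose from 44.7 ± 10.3 to 177 ± 9.99 CPM (log2 fold change 1.98, SE 0.17, adjusted p = 0.000430). P4ha1 rose by 1.09 and Aldoc by 1.04 (adjusted p = 0.0771 with controls 2 and 3 summed), and Tpi1 fell by 0.60.

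**Figure D4:**
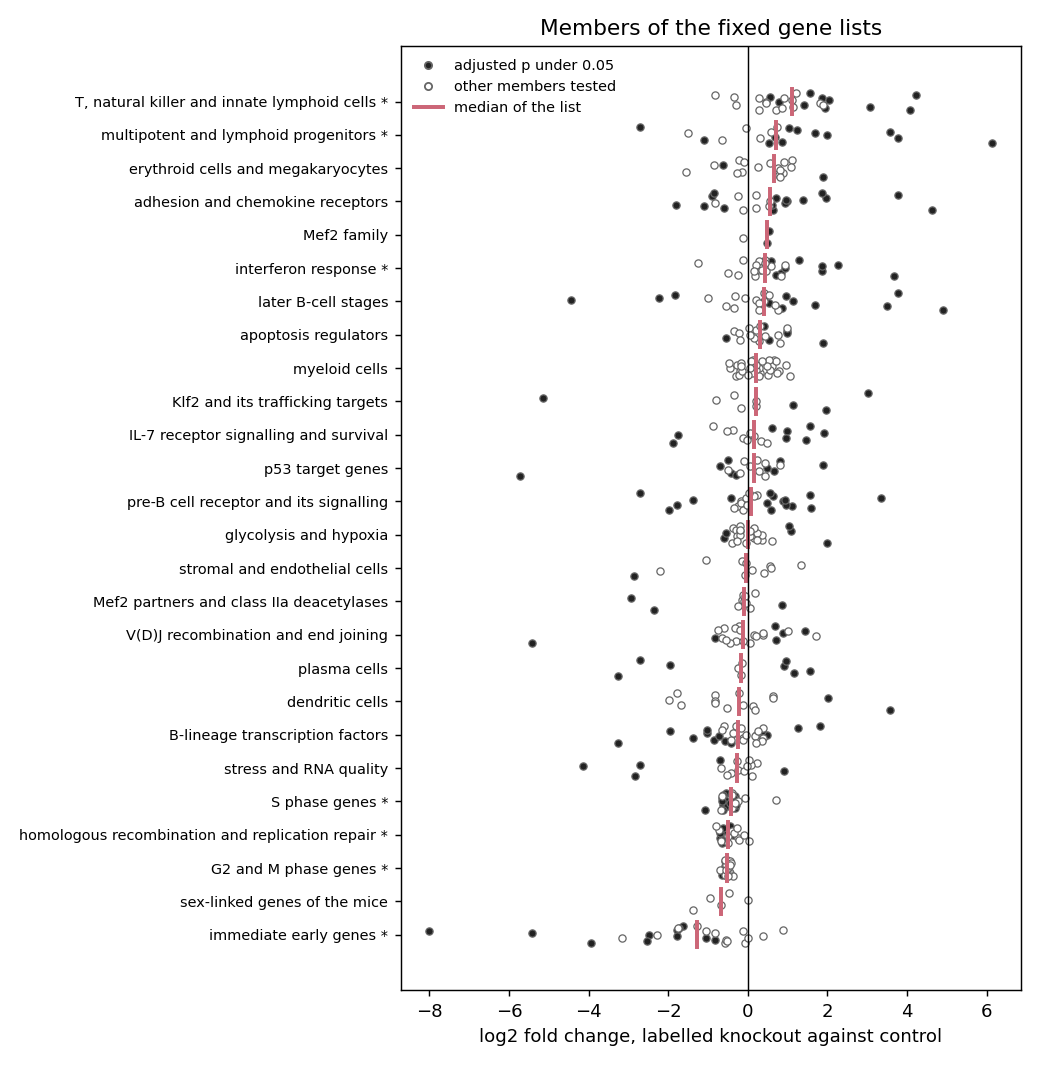
Log2 fold changes, labelled knockout against control, of the tested members of the 26 fixed lists, ordered by list median. Filled points are called members, open points are other tested members, red bars are list medians and an asterisk marks the 7 lists called by camera; medians run from −1.27 (immediate early genes) to 1.11 (T, natural killer and innate lymphoid cells).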

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

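The tests of explanations below were chosen after the patterns had been seen, and the results of the splits for gene lists and of the immediate early genes without replicate 1 were not known when their predictions were written. The values in columns outside the main measurement were also singled out afterwards. Knockout 3 had 27.7% of its gene reads outside exons and knockout 1 had 23.1%, against 19.5% in knockout 2 and 19.0% to 19.7% in controls. Reads of Gm26924 numbered 15430 per 1e6 gene reads in knockout 3 and 5159 in knockout 1, against 3166 in knockout 2 and 1061 to 5150 in controls. Knockout 3 also had the highest Lars2 level, 12270 CPM against 373 to 2230 CPM in the other libraries.

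The real split called 3505 genes, and the highest of the other 9 splits of the 6 libraries called 0 with edgeR (13 to 1167 genes at an unadjusted p under 0.05). Only 1 of 10 splits reached the real count, but 10 splits are too few for a share under 0.05. For the gene lists the real split called 7, the highest other split called 10, and 5 of the 10 splits called at least 7. Each of the other 9 splits mixes the groups, so it keeps part of their difference and counts the rest as spread. Their counts therefore do not show what would be called without any difference.

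The first pattern is that exon reads of Mef2c were not lower in the libraries labelled knockout, and those of Mef2d were lower only by 0.12 on the log2 scale, without a call. A library carrying the label of the other group is argued against for single libraries, since 0 of 6, set against group means on genes called without that library, correlated better with the other group, but that test cannot see an exchange of all labels, which stays open. Transcripts that lack internal exons but are still counted remain a candidate explanation. The share of Mef2c exon reads that cross a junction, relative to the share of the library, was 0.557 ± 0.0303 in controls and 0.428 ± 0.0203 in libraries labelled knockout, a change at percentile 0.190 of 5270 well-covered genes. For Mef2d the shares were 0.494 ± 0.0159 and 0.437 ± 0.0157 (percentile 1.61). Both falls are what such transcripts predict, but a lower junction share does not by itself show that exons are missing. Whether any are missing stays open, because exon-level counts were not analysed here.

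The second pattern is the fall of immediate early genes. An excess in the replicate 1 control library alone is argued against, because 10 of the 11 members that fell were also called lower without replicate 1. The controls left in that fit are the near-identical controls 2 and 3, so its calls lean on a small spread, but Klf4 stood at 73.3 and 71.3 CPM in them against 4.83 and 5.92 CPM in knockouts 2 and 3. Longer or warmer handling of the control cells would raise Fos, Jun, Egr1, Ier2 and Atf3 together, and without replicate 1 the 95% intervals of 3 of these 5, Egr1 (0.04 to 0.61), Ier2 (−0.41 to 0.19) and Atf3 (0.41 to 3.29), excluded a 2-fold fall. Handling stays open all the same, as does loss of Mef2 activity, named by the group labels and untested, because Atf3 had few reads, Fos (−4.09) and Jun (−0.82, adjusted p = 0.0012) were called lower in that fit, and control 1 exceeded knockout 1 for all 5.

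The third pattern is the rise of T-cell and progenitor genes. T cells among the sorted cells are argued against, because the most abundant of Cd3d, Cd3e and Cd3g reached a mean of 0.574 CPM in the libraries labelled knockout, against 279 CPM for Lat, though Trbc2 rose from 0.122 to 1.78 CPM (adjusted p = 0.000676). Multipotent progenitors among the sorted cells, which the CD19 gate of the sort is meant to remove, are not excluded by these values, because most of the 7 genes of such cells (Cd34, Meis1, Hlf, Mecom, Mpl, Gata2 and Hoxa9), of which 0 were called higher, lay near the floor or had too few reads for the test. With the replicate block Meis1 and Hoxa9 were called higher (adjusted p = 0.0118 and 0.0192) and Cd34 lower (0.0299). A larger share of cells just past commitment to the B lineage, or a direct effect of the genotype, may account for it as well, and neither was tested.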

How the results depend on the processing

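The fits with controls 2 and 3 summed, with unique reads and with a term for replicate 1, and the list tests without a replicate number in both groups, were chosen after the data were seen. The count of 3505 changed genes stayed within 1.5 times under other scalings, DESeq2, limma-voom, no filter, a threshold of 0.1, other treatments of repeated symbols, unique reads and removal of immunoglobulin and sex-linked genes (3143 to 4736). It was 6283 with the replicate block, 6975 with the term for replicate 1, 2048 with controls 2 and 3 summed, 2299 under the strict filter, which tests fewer genes, and 1804 with a minimum log2 fold change of 1. Leaving out libraries gave 793 (without replicate 3 in both groups) to 6389 (without replicate 1), with 1978 without control 2, 2010 without control 3 and 2268 without knockout 3. The Mef2c change ran from 0.44 to 0.68 with libraries left out. Its call was lost with controls 2 and 3 summed (0.45) and, by construction, with a minimum of 1 (0.52). Mef2d was called nowhere. The 7 called lists became 0 with an estimated correlation, which exceeded the preset in all 7 (0.0267 to 0.647). In the apoptosis list the estimate lay below the preset (−0.0243), and the camera p rose as well. With fry 14 were called, and further causes of these differences were not tested. With libraries left out 7 to 9 lists were called, not always the same ones. The apoptosis list was called without knockout 1 (adjusted p = 0.0229) or replicate 1 (0.0248), the adhesion list without knockout 2 (0.0403) or replicate 2 (0.0499), and the stress list without replicate 3 (0.0472). The myeloid list, uncalled at first, was called higher without knockout 2 or without replicate 2 (adjusted p from 0.000685 to 0.994 over the libraries left out), and the cause was not tested.

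Among 104 named genes, 2458 results under alternatives kept their direction and call, 116 lost the call and 2 gained it, and none reversed. Of the losses, 29 came without replicate 2 and 31 without replicate 3 in both groups. Most named genes were picked because they were called, and several alternatives reuse the same counts, so the total of kept calls is no measure of robustness. The 32 genes that lost a call, Mef2c not counted, included many cell cycle genes of small change, such as Ccnb2, Birc5 and Aurka. Beyond the counts and lists given with the results, the replicate block changed no call of these genes. Among genes named outside that rule it called Meis1, Hoxa9, Rag1 and Rag2 higher and Cd34, Mpo, Jun and Ighm lower. Of changes of 1.5-fold, 10.4% were recovered in the simulation.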

Other observations

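The gene families here were chosen after their values were seen, and the predictions of the 2 hypotheses at the end were written before their tests were run. Several families of immune genes held members that rose. All 8 tested Gimap genes, GTPases of lymphocytes that lie next to each other on chromosome 6, rose, from 1.07 (Gimap5) to 5.27 (Gimap7) on the log2 scale, and 7 of them were called with controls 2 and 3 summed. Of 11 Gbp genes, interferon-inducible GTPases, 10 rose and 0 fell, with a median log2 fold change of 2.97 over the family, and 9 were called on unique reads. Of 6 Serpina3 genes on chromosome 12, which share reads in part, 5 rose, and of 10 Toll-like receptor genes 6 rose and 0 fell, among them Tlr7 (2.96) and Tlr4 (1.17). Of 31 interleukin receptor genes 13 rose and 0 fell, and 16 rose and 3 fell with the replicate block. Histone genes, most of whose transcripts lack a poly(A) tail, had 16 of 63 lower and 2 higher, and 27 lower with the replicate block.

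Many variable segments of the immunoglobulin loci were lower in the libraries labelled knockout. Of 100 tested heavy chain segments (Ighv) 54 fell and 7 rose, with a median of −1.47, and of 60 kappa segments (Igkv) 28 fell and 1 rose, with a median of −1.61 (18 lower of 73 with controls 2 and 3 summed, and 2 higher with the replicate block). Segments share sequence, so single segments are uncertain, but 50 heavy and 25 kappa segments were called lower on unique reads, out of 96 and 52 tested. The mu constant gene Ighm was not called (log2 fold change −0.36, SE 0.20, adjusted p = 0.242, and 0.0177 with the replicate block), and the kappa constant gene Igkc fell by 1.12 (SE 0.17, adjusted p = 0.00419).

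Around the targeted genes, 27.4% of 62 genes tested within 10 Mb of Mef2c and 25.9% of 228 within 10 Mb of Mef2d were called, against 25.3% elsewhere.

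As a hypothesis, heavy chain segments far from the D segments may fall more than near ones. The median log2 fold change was −1.75 over 56 far segments (Ighv1 and Ighv8 families) and −0.69 over 17 near segments (Ighv2 and Ighv5 families), a difference of −1.06 with a two-sided permutation p of 0.0362 over segments. Segments are not independent replicates, and the p is unadjusted over the 2 hypotheses tested, so the difference remains a lead only.

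A further hypothesis was that sarcomere and muscle enzyme genes fall as a class when Mef2 is lost, prompted by Srpk3 and Rbm24 among the largest falls. Of 64 listed genes 21 were tested, 3 were lower (Mybpc2, Pgam2 and Tnnt2) and 2 higher (Pygm and Tnni3), with a median of 0.01 and a camera p of 0.947 in limma, permutation of libraries not being informative with 3 against 3. The 21 tested genes gave no sign of a fall as a class. The other listed genes were not tested, and genes near the floor in controls cannot show a fall.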
